A study of Rattus norvegicus with 12 samples.

How the data were processed

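Total RNA from the whole spiral ganglion of hearing and kanamycin-deafened rats at P32 and P60 was measured in 12 libraries, 3 biological replicates for each of 4 groups. Per the labels, the organ of Corti, spiral ligament and bone were removed by microdissection, RNA was isolated with Trizol and a column with DNase, ribosomal RNA was depleted with Ribo-Zero Gold, and each library was sequenced on 3 lanes. The deposited count table holds raw reads per gene for 32883 Ensembl gene IDs in 12 columns, 1 per library, so lanes were already summed per the file headers. The submitters' notes name bcl2fastq 2.20, Trimmomatic, STAR 2.7.0b, SAMtools, featureCounts, Subread 1.6.3 and DESeq2 1.32.0. They give no role or order for these tools, and the genome build, the annotation and the strandedness are not given in the sources used here.

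A second deposited table holds a normalized signal for 21829 gene symbols in 11 libraries, made by the authors by dividing the counts by 1 size factor per library. P32 hearing replicate 3 has no column there. Multiplying each value by the library's median-of-ratios factor gave whole reads within a tolerance of 0.1 for 100% of values (largest deviation 0.0835), and each of the 21829 symbols matched exactly 1 gene of the count table, which paired symbols with IDs. The 11054 IDs left without a symbol hold 0.00632% of the reads, and 6424 of the 32883 have no read in any library. Tests used the raw counts.

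Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups (17789 of 32883), libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 12 libraries. Deafened and hearing rats were compared at each age, P60 with P32 in each condition, and the effects of deafening between the ages by the interaction term. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Levels are TMM-scaled CPM as mean ± SD. The SE of a log2 fold change is its size divided by the square root of F. All 4 groups share 1 estimate of the spread, so a library can change the calls of a comparison it is not part of. A gene's fold change and its ratio of mean CPM can differ slightly.

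For groups of genes, 38 lists of cochlear, neural, immune, connective tissue and housekeeping genes were written from general knowledge, with 1081 members, of which 936 were tested. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists, with at least 5 tested members each. Some genes are in more than 1 list, and many immune genes are expressed by more than 1 cell type. Camera with an estimated correlation and fry were alternatives. Median log2 fold changes are over the tested members of a list.

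Named genes followed a rule. For deafened against hearing rats it took the 8 largest rises and the 8 largest falls among genes past the threshold with no overlap of the groups, a mean of at least 1 CPM in the higher group and a symbol that is not a placeholder. It added up to 4 members per list with the smallest adjusted p and 20 genes whatever their p. For age it took the 5 largest each way and up to 3 members per list, and for the interaction the 8 smallest adjusted p past the threshold. Some genes that the rule names are not reported here. The comparisons, tests, lists, rule and the other settings below were chosen before the data were examined.

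These settings were other normalizations, filters, DESeq2 1.42.0, limma voom, fits of the compared groups alone, a replicate block, a fold minimum, the authors' normalized values with pseudocounts of 1 and 5, and leaving out each replicate in turn. Settings added later are named in the closing section. The pipeline was tested on simulated data at P60: with 12 libraries edgeR recovered 17.9%, 58.2% and 90.9% of genes changed 1.5, 2 and 4 times, with 7 false calls among 17789 genes, and without P32 hearing replicate 3 it recovered 67.2%, 88.1% and 97.0%, with 8 among 18057. The simulated counts followed the model that edgeR fits, with 1 spread per gene for all libraries and no outlying library. Few false calls are thus built in, and the recovered shares may not hold for the real libraries. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Transcript isoforms, allele differences and reads were not analysed here.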

Results

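Transcript levels were measured in the whole spiral ganglion of Sprague-Dawley rats, the body of auditory neurons inside the cochlea with its glia, vessels and connective tissue. Deafened rats had received kanamycin, an aminoglycoside antibiotic that destroys the sensory hair cells, at 400 mg/kg on each day from P8 to P16. Their hearing littermates had no injection. Ganglia were taken at P32 or P60, which gave 4 groups of 3 biological replicates and 12 libraries. The number of animals behind each replicate is not given in the sources used here. The libraries held 15646405 to 43453272 counted reads, so that a gene at 1 count per 1000000 reads (CPM) rested on about 15.6 to 43.5 reads in a library. The comparisons ask how the ganglion of deafened rats differs from that of uninjected littermates at each age. They also ask whether that difference changes between the ages, and how the ganglion changes with age in each condition. Hair cell loss, direct action of the drug and the injections go together in this design and cannot be told apart. The effect of deafening below stands for all of them.

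The library P32 hearing replicate 3 stood apart from the other 11. Its median correlation with the other libraries, across genes on log2 CPM, was 0.949, against at least 0.977 for each other library, and the first principal component (41.1% of the variance) placed it at 104 with the others between -18.8 and 8.4. Mitochondrial genes with a symbol starting with Mt took 3.16% of its reads, against 1.30% to 1.64% in the others. This share leaves out its most abundant gene, AY172581.24, which alone took 3.25%, against at most 1.77% in the others. Structural and small noncoding RNA took 4.18%, against 1.54% to 2.10%, and haemoglobin 0.237%, against 0.0378% to 0.113%. This library is the one that the authors' normalized table leaves out. It was kept in the tests, and the count of genes past the threshold in each comparison is also given without it. No pair of replicates within a group agreed within sampling noise, with a chi-square per gene of at least 4.24, so each library counts as 1 replicate. P60 deaf replicate 3 stood apart in a smaller way, at 49.4 on the second component (20.1% of the variance) with the others between -25.8 and 26.7.

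At P32 the ganglion of deafened rats held more transcript of some genes of phagocytes and complement and of the injury gene Atf3, and less of a few neuronal and contractile genes, than that of hearing littermates. As lists, phagocyte and complement genes did not pass with an estimated correlation (camera adjusted p = 0.354 for both). Gpnmb (ENSRNOG00000008816), a glycoprotein of lysosome-rich phagocytes, stood at 10.5 ± 2.42 CPM in hearing and 45.1 ± 0.256 CPM in deafened rats (SD, n = 3 each), a 4.31-fold rise. Atf3 (ENSRNOG00000003745), a transcription factor induced in injured neurons and Schwann cells, rose 3.78-fold from 3.59 ± 0.825 to 13.8 ± 2.11 CPM. Calb2 (ENSRNOG00000016977), which encodes the calcium-binding protein calretinin of spiral ganglion neurons, was lower in deafened rats, at 1326 ± 147 CPM against 2912 ± 894 CPM (log2 fold change -1.14 ± 0.20 SE, edgeR adjusted p = 0.0414). By edgeR's quasi-likelihood test, 56 of 17789 genes were past an adjusted p of 0.05, 40 higher and 16 lower in deafened rats.

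Besides Gpnmb and Atf3, the largest rises at P32 were in Gpr83, a G protein-coupled receptor (7.59-fold, 0.831 ± 0.458 to 6.76 ± 0.635 CPM), and Rgs9, a regulator of G protein signalling (4.88-fold, 2.64 ± 0.866 to 13.1 ± 1.71 CPM). The complement gene C4b, whose reads could be shared with close copies, rose 3.87-fold (edgeR adjusted p = 0.0117). Hk3, a hexokinase of myeloid cells, rose 3.69-fold, Mab21l3 3.61-fold and Tlr5, the receptor for bacterial flagellin, 3.15-fold, with edgeR adjusted p between 0.0347 and 0.0464. The largest fall was in Ocm2, from 3.04 ± 2.12 to 0.208 ± 0.0855 CPM (log2 fold change -3.89 ± 0.68 SE, edgeR adjusted p = 0.0397). It was 14.8-fold with all libraries and 9.43-fold with P32 hearing replicate 3 left out. Ocm2 is close in sequence to oncomodulin, a protein of outer hair cells, and its reads could be shared with that gene. Hsd17b2, an enzyme that inactivates sex steroids, was 7.55-fold lower. Myl1, a myosin light chain of fast muscle fibres, was 5.22-fold lower (3.49-fold without that library), from 68.7 ± 40.8 to 13.2 ± 2.79 CPM, and Ckmt2, the mitochondrial creatine kinase of striated muscle, was 4.59-fold lower. Ces1f, a carboxylesterase, was 3.04-fold lower, Zfp804a 2.34-fold and Agbl1, an enzyme that trims glutamate chains from tubulin, 2.27-fold.

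Most immune lists were higher at P32 with the preset correlation, B cells and granulocytes excepted. None passed with an estimated correlation or by fry. Of 38 macrophage genes, 2 rose past the threshold over all genes tested, 8 rose adjusted over the list alone, and none fell. The 2 were the lysosomal protein Cd68 (3.07 ± 0.345 to 7.89 ± 1.28 CPM) and the sialic acid receptor Siglec1 (3.79 ± 0.302 to 10.8 ± 0.249 CPM). The list as a whole was higher (median log2 fold change 0.28, camera adjusted p = 3.13e-08), though not with an estimated correlation (adjusted p = 0.357). With P32 hearing replicate 3 left out, 21 of the 38 were higher and the median was 0.67. Complement genes gave 5 rises of 35 tested (10 adjusted over the list alone), and 10 without that library, where the median went from 0.30 to 0.47. They included C3, the central component of the cascade (47.7 ± 9.02 to 108 ± 7.10 CPM), C2 (2.19-fold) and C1r (1.69-fold). For that list camera gave an adjusted p of 3.91e-06, and an adjusted p = 0.354 with an estimated correlation. Among 25 genes of phagocyte lysosomes and lipid handling, 3 rose (7 rose and 1 fell adjusted over the list alone): Gpnmb, Lgals3, the lectin galectin-3 (10.4 ± 1.79 to 30.3 ± 1.34 CPM), and Abca1, a cholesterol exporter (319 ± 61.1 to 621 ± 17.2 CPM). Its camera adjusted p was 3.32e-05, with an adjusted p = 0.354 with an estimated correlation. Of the 25, 8 were higher and 1 lower without that library.

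Genes of the interferon response had the highest median of the lists at P32, 0.62 on the log2 scale (camera adjusted p = 1.49e-12, adjusted p = 0.354 with an estimated correlation), and 38 of the 40 members lay above 0. A single member, Irf8, a transcription factor of myeloid cells, passed the threshold over all genes (7.88 ± 0.588 to 14.3 ± 0.240 CPM). Of the list 10 did adjusted over the list alone, and 14 did over all genes without P32 hearing replicate 3. Of 24 activity-regulated early genes, Atf3 and Fos (6.12 ± 1.19 to 12.5 ± 0.952 CPM) rose, and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0173, adjusted p = 0.394 with an estimated correlation). Btc, the growth factor betacellulin, rose 2.47-fold and was the 1 gene of 26 past the threshold among nonmyelinating and repair glia (4 adjusted over the list alone). That list was higher by camera (adjusted p = 0.00272, adjusted p = 0.354 with an estimated correlation). Cd4, a receptor of T cells and of rat macrophages, was the 1 of 20 T and NK cell genes to rise (2.09-fold; 3 adjusted over the list alone). Tlr5 was the 1 of 29 toll-like receptor and inflammasome genes (5 adjusted over the list alone), and Tbx18 the 1 of 15 genes of the stria vascularis and ligament (1.58-fold; 3 rose and 1 fell adjusted over the list alone).

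Neuronal genes were lower as groups at P32, and few single genes passed. None of 26 general neuronal genes passed over all genes tested, 10 fell adjusted over the list alone, and the median was -0.37 (camera adjusted p = 4.17e-05, adjusted p = 0.354 with an estimated correlation). The synaptic vesicle fusion protein Snap25 had 1272 ± 197 CPM in hearing and 766 ± 49.3 CPM in deafened rats (edgeR adjusted p = 0.0816), and the neurofilament Nefl 1746 ± 392 and 1259 ± 57.3 CPM (edgeR adjusted p = 0.323). Levels in P32 hearing replicate 3 moved with this group. Without that library 11 of the 26 were lower and 1 higher, Snap25 fell with an edgeR adjusted p of 0.0131 and Nefl with 0.00798. Of 24 genes of type I and type II spiral ganglion neurons Calb2 fell (2 adjusted over the list alone), and the list did not pass with all libraries (median -0.12, camera adjusted p = 0.214). It did without that library, with 5 lower and a median of -0.29 (camera adjusted p = 1.80e-04, adjusted p = 0.0793 with an estimated correlation). Neuronal ion channels (0 of 40; 9 lower without that library) had a median of -0.19 (camera adjusted p = 0.0403, adjusted p = 0.553 with an estimated correlation). Synaptic genes (0 of 39; 1 higher and 4 lower without that library) had a median of -0.16 (camera adjusted p = 0.0102, adjusted p = 0.394 with an estimated correlation). The medians were -0.35 for ion channels and -0.30 for synaptic genes without that library.

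Oxidative phosphorylation genes were lower at P32, with 0 of 55 past the threshold over all genes, 38 lower adjusted over the list alone and a median of -0.61 (camera adjusted p = 1.83e-16, adjusted p = 0.354 with an estimated correlation). The 44 cytosolic ribosomal protein genes had a median of -0.51 (camera adjusted p = 4.69e-04, adjusted p = 0.558 with an estimated correlation), and this direction rested on P32 hearing replicate 3: without it the median was 0.11 and the list was higher (camera adjusted p = 2.77e-06). Transcripts of the mitochondrial genome went from a median of -0.59 to -0.07 without that library, where the list no longer passed (camera adjusted p = 0.223), and the oxidative phosphorylation list to -0.21. Erythroid genes were lower (median -0.56, camera adjusted p = 0.00356, adjusted p = 0.354 with an estimated correlation), with 0 of 17 past the threshold, and had a median of -0.20 without that library, which held the highest share of haemoglobin.

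The organ of Corti had been removed by dissection, and 4 genes of hair cells were low at P32. Otof, which releases transmitter at the hair cell synapse, had 3.45 ± 0.749 CPM in hearing and 2.69 ± 1.49 CPM in deafened rats, Myo7a 2.75 ± 0.215 and 4.86 ± 1.54 CPM, and the outer hair cell motor Slc26a5 1.30 ± 0.473 and 0.979 ± 0.214 CPM. Pou4f3, a hair cell transcription factor, had 0.378 ± 0.145 and 0.382 ± 0.285 CPM. None of these 4 passed (edgeR adjusted p from 0.334 to 0.902), and none of 27 hair cell genes passed. The myelin gene Mbp (6908 ± 829 and 7058 ± 382 CPM) did not pass either (edgeR adjusted p = 0.921), nor did Tubb3, Rbfox3 and Scn4b of neurons (0.431 to 0.759) or Jun, Cd74 and C1qa (0.107 to 0.279). Of these, Scn4b passed with P32 hearing replicate 3 left out (1.47-fold lower, edgeR adjusted p = 0.00702), and so did C1qa (1.84-fold higher, edgeR adjusted p = 0.00464). Aif1 and Ptprc, markers of macrophages and of white blood cells, had edgeR adjusted p of 0.901 and 0.815 with all 12 libraries, and 0.012 and 0.00482 without P32 hearing replicate 3, where they rose 1.68-fold and 1.82-fold.

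Other immune lists were higher at P32 with the preset correlation alone, with few genes past the threshold. Class II presentation had 0 of 10 over all genes and 1 adjusted over the list alone (median 0.32, camera adjusted p = 0.00281, adjusted p = 0.357 with an estimated correlation), and class I had 0 of 22 and 2 (median 0.20, camera adjusted p = 6.27e-04, adjusted p = 0.357 with an estimated correlation). Chemokines and cytokines had 0 of 32 and 1 (median 0.31, camera adjusted p = 0.00773, adjusted p = 0.395 with an estimated correlation). With P32 hearing replicate 3 left out, class I had 6 of 22 and a median of 0.42, class II 2 of 10 and 0.59, chemokines 3 of 33 and 0.40, and T and NK cells 1 of 22 and 0.64 against 0.34 with all libraries. Toll-like receptors then had 5 of 29 higher, fibroblast and matrix genes 4 of 23, early genes 4 of 24 (1 lower), axon injury 3 of 23 with a median of 0.18, and cell cycle and repair glia 2 each, and 6 of 55 oxidative phosphorylation genes were lower. For T and NK cells camera gave an adjusted p of 0.00281 and for toll-like receptors 5.55e-05, each with an adjusted p = 0.354 with an estimated correlation. Also higher were cell cycle genes (0 of 34, median 0.18, camera adjusted p = 0.00798, adjusted p = 0.395 with an estimated correlation) and fibroblast and matrix genes (0 of 23, median 0.20, camera adjusted p = 0.0198, adjusted p = 0.437 with an estimated correlation). Axon injury genes had Atf3 alone of 23 (median 0.01, mean 0.15, camera adjusted p = 0.0264, adjusted p = 0.354 with an estimated correlation). Neurotrophic factors (0 of 26, camera adjusted p = 0.0264, adjusted p = 0.437 with an estimated correlation) went from a median of 0.13 to -0.02 without P32 hearing replicate 3, where they no longer passed (camera adjusted p = 0.731). Cholesterol synthesis was lower (0 of 25, median -0.17, camera adjusted p = 0.00208, adjusted p = 0.354 with an estimated correlation).

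Lists that did not pass at P32 included myelinating Schwann cells (median 0.05), B cells (0.07), granulocytes (-0.45), endothelial and mural cells (0.12), cartilage (0.11), heat shock and dissection stress (-0.18), nonsensory cells of the organ of Corti (0.23), hair cells (-0.12) and sex-linked genes (-0.53), with camera adjusted p from 0.0727 to 0.475. In 5 lists the median and the mean had opposite signs: the stria and ligament (0.23 and -0.07), central glia (0.06 and -0.01), osteoblasts (0.02 and -0.01), osteoclasts (0.08 and -0.02) and skeletal muscle, with Myl1 as its 1 fall (0.04 and -0.11). Camera gave adjusted p from 0.0691 to 0.753 for those 5. With P32 hearing replicate 3 left out 2 of them passed, the stria and ligament (median 0.31, mean 0.19, camera adjusted p = 0.00905) and osteoblasts (0.10 and 0.13, camera adjusted p = 0.0156), and skeletal muscle alone kept opposite signs.

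Of the 38 gene lists, 23 were past a camera adjusted p of 0.05 at P32, 15 higher and 8 lower, none of them with an estimated correlation. Without P32 hearing replicate 3 the count of genes was 641 (279 higher, 362 lower), and all 56 were among them. The count was 0 when only the 6 libraries of that age were fitted, with 2302 genes at an unadjusted p under 0.05 in the fit of 12 libraries, and 425 by DESeq2. It was 11, 5 and 6 without P32 deaf replicate 1, 2 or 3, 29 and 20 without P32 hearing replicate 1 or 2, 28 and 35 without P60 deaf replicate 1 or 2, and 27, 34 and 21 without P60 hearing replicate 1, 2 or 3.

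**Figure D1:**
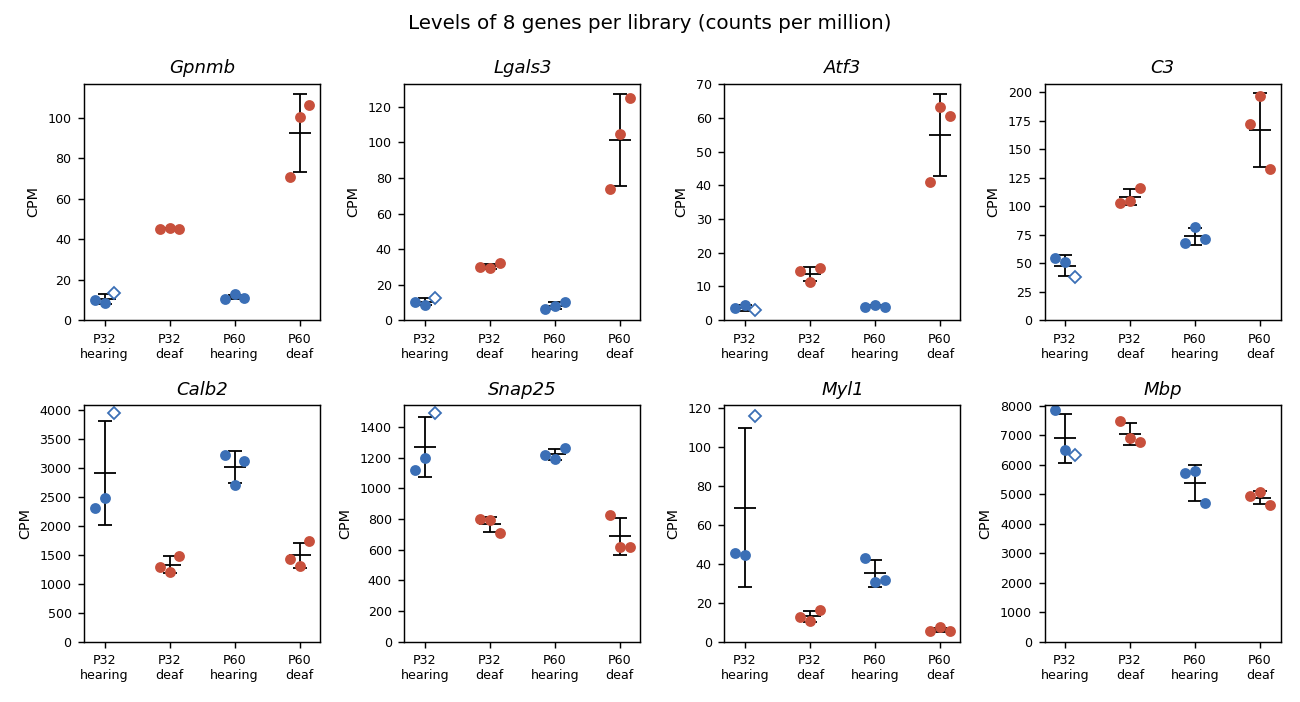
Level of 8 genes in each of the 12 libraries, in CPM on a linear axis from 0, with hearing rats in blue, deafened rats in red, and the mean ± SD of each group of 3 in black. Gpnmb, Lgals3, Atf3 and C3 were higher in deafened rats at both ages, Calb2 and Myl1 were lower at both, Snap25 passed the test at P60, and the myelin gene Mbp did not differ at either age; the white diamond marks P32 hearing replicate 3.

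At P60 genes of phagocytes and complement were again higher in deafened rats, and some neuronal genes lower. The neuronal lists did not pass with an estimated correlation (adjusted p = 0.0762 for general neuronal genes), and 3 of 26 general neuronal genes fell over all genes. Lgals3 (ENSRNOG00000010645) rose 12.4-fold, from 8.15 ± 1.75 CPM in hearing to 101 ± 25.8 CPM in deafened rats (SD, n = 3 each), Gpnmb 8.08-fold, from 11.4 ± 1.11 to 92.4 ± 19.2 CPM, and Atf3 13.4-fold, from 4.09 ± 0.360 to 54.9 ± 12.1 CPM. Gfap (ENSRNOG00000002919), an intermediate filament of nonmyelinating and reactive glia, rose 2.42-fold, from 1398 ± 139 to 3385 ± 350 CPM. The neuronal genes Snap25 (ENSRNOG00000006037; 1224 ± 35.7 to 687 ± 120 CPM, 1.78-fold) and Calb2 (3018 ± 273 to 1489 ± 216 CPM, 2.03-fold) were lower in deafened rats. So was Slc17a7, the vesicular glutamate transporter VGLUT1 (673 ± 66.4 to 313 ± 44.3 CPM, 2.15-fold). By edgeR, 578 of 17789 genes were past an adjusted p of 0.05, 399 higher and 179 lower.

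The largest rises at P60 beside those 3 were in Gpr83, from 0.784 ± 0.0888 to 40.4 ± 12.9 CPM (log2 fold change 5.67 ± 0.36 SE, edgeR adjusted p = 7.89e-06), Ucn2, the peptide hormone urocortin 2, and the growth factor Fgf5. The last pair were near the floor in hearing rats, at 0.0529 ± 0.0667 and 0.0387 ± 0.0432 CPM with 1 library at 0 each, and had 4.08 ± 1.45 and 1.34 ± 0.374 CPM in deafened rats. Tmprss11f, a transmembrane serine protease, rose 13.3-fold to 6.92 ± 1.92 CPM, and the class I gene RT1.M2, whose family shares reads, 7.75-fold to 1.90 ± 0.387 CPM. The largest falls were in Hsd17b2 (5.92-fold), Myl1 (35.2 ± 6.92 to 5.98 ± 1.19 CPM, 5.84-fold), and Col6a5, a collagen VI chain (4.25-fold). Next were Srl, the calcium-binding protein sarcalumenin of the sarcoplasmic reticulum (39.1 ± 3.57 to 9.90 ± 1.67 CPM, 3.94-fold), Ckmt2 (3.61-fold) and Fndc3c1 (3.57-fold, edgeR adjusted p = 0.0444). Th, tyrosine hydroxylase, which makes catecholamines and marks type II spiral ganglion neurons and sympathetic fibres, was 2.88-fold lower (14.5 ± 1.09 to 5.03 ± 0.973 CPM), and the orexin receptor Hcrtr2 2.80-fold lower.

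Macrophage genes had the largest median of the lists at P60. Of 38 tested, 17 rose over all genes (33 adjusted over the list alone; 8 over all genes with P60 deaf replicate 3 left out) and none fell, with a median of 1.06 on the log2 scale (camera adjusted p = 3.80e-24, adjusted p = 0.0762 with an estimated correlation). Among them were Csf1r, the receptor for the growth factor of macrophages (100 ± 11.4 to 184 ± 11.7 CPM), Laptm5, a lysosomal protein of white blood cells (19.0 ± 1.90 to 41.6 ± 3.83 CPM), Cd68 (3.65 ± 0.508 to 9.36 ± 1.11 CPM) and the inhibitory receptor Lilrb4 (4.90-fold). Aif1 and Ptprc had 2.02-fold and 2.18-fold higher fitted levels that did not pass (edgeR adjusted p = 0.135 and 0.105). With P32 hearing replicate 3 left out both did, at 1.98-fold and 2.15-fold (edgeR adjusted p = 0.000175 and 6.31e-05). Of 25 genes of phagocyte lysosomes and lipid handling, 10 rose (16 adjusted over the list alone; 6 over all genes with P60 deaf replicate 3 left out), among them Abca1 (353 ± 22.4 to 856 ± 99.2 CPM) and Trem2, a lipid-sensing receptor of microglia and macrophages (5.96 ± 0.977 to 15.5 ± 2.39 CPM). That list held with an estimated correlation (camera adjusted p = 4.46e-12 preset, adjusted p = 0.0416 with an estimated correlation), but not with P32 hearing replicate 3 left out (adjusted p = 0.0971 with an estimated correlation).

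Complement genes were the second of 3 lists that held in this way, with 12 of 35 higher (16 adjusted over the list alone), a median of 0.57, a camera adjusted p of 2.11e-13 and an adjusted p = 0.0416 with an estimated correlation (0.0971 with P32 hearing replicate 3 left out). C3 went from 73.6 ± 7.51 to 167 ± 32.5 CPM, C1r from 72.9 ± 6.87 to 146 ± 12.7 CPM, and C1qa, a chain of the initiating complex, from 39.8 ± 6.28 to 85.8 ± 10.5 CPM. C2 rose 2.55-fold, and C4b went from 5.13 ± 2.30 to 20.7 ± 2.52 CPM. Antigen presentation by class II rose as a group (median 0.80, camera adjusted p = 1.31e-07, adjusted p = 0.0797 with an estimated correlation). Of its 10 genes, Cd74, the invariant chain (49.5 ± 8.95 to 102 ± 14.7 CPM), and Ifi30, a lysosomal thiol reductase (1.73-fold), passed over all genes, and 9 did adjusted over the list alone. Among 22 class I and processing genes RT1.CE10 rose (1.79-fold; 6 adjusted over the list alone; camera adjusted p = 5.28e-06, adjusted p = 0.162 with an estimated correlation), and its reads could be shared within the RT1 family. Of 40 interferon response genes 4 rose (8 adjusted over the list alone), namely Irf8 (2.03-fold), Irf1 (1.74-fold), Parp14 (1.67-fold) and Gbp2, an interferon-induced GTPase (26.7 ± 7.99 to 63.4 ± 10.3 CPM; camera adjusted p = 4.46e-12, adjusted p = 0.223 with an estimated correlation).

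Chemokine, T and NK cell and toll-like receptor lists were higher with the preset correlation, and none of the 3 passed with an estimated correlation. Of 32 chemokine and cytokine genes, 5 rose (9 adjusted over the list alone). Cxcl14 went from 15.8 ± 1.70 to 40.5 ± 6.58 CPM and Cxcl10, an interferon-induced chemokine for T cells, from 1.66 ± 0.859 to 8.90 ± 1.58 CPM, and Ccl4 and Ccl7, chemokines for monocytes, rose to means of 0.700 and 1.24 CPM (camera adjusted p = 1.50e-08, adjusted p = 0.0797 with an estimated correlation). Of 20 T and NK cell genes, Cd4 (24.7 ± 2.48 to 50.4 ± 7.32 CPM), the T cell receptor Cd6 (2.30-fold) and the NK cell receptor Klrd1 (0.108 ± 0.0579 to 0.544 ± 0.220 CPM) rose, and 7 did adjusted over the list alone (camera adjusted p = 2.07e-05, adjusted p = 0.0708 with an estimated correlation). Of 29 toll-like receptor and inflammasome genes 5 rose (15 adjusted over the list alone), among them the adaptor Myd88 (1.57-fold), the kinases Irak4 (1.66-fold) and Irak3 (1.43-fold) and the sensor Nlrp3 (1.58-fold), with a camera adjusted p of 4.46e-12 and an adjusted p = 0.069 with an estimated correlation. The receptor Cd22 and the adaptor Blnk were the 2 of 19 B cell genes to rise, and that list did not pass (median -0.02, mean 0.17, camera adjusted p = 0.584), nor did granulocyte genes (1 of 13, Csf3r, 1.94-fold; camera adjusted p = 0.0769).

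Neuronal genes fell as groups at P60 with the preset correlation and by fry, and not with an estimated correlation. Fry gave an adjusted p of 0.00867 for general neuronal genes, 0.0282 for spiral ganglion neurons, 0.0188 for synaptic genes and 0.047 for ion channels. Of 26 general neuronal genes, Slc17a7, Snap25 and Elavl4, an RNA-binding protein of neurons (224 ± 15.8 to 143 ± 19.0 CPM), were lower over all genes, 20 were lower adjusted over the list alone, and the growth cone protein Gap43 was higher (7.50 ± 0.622 to 19.4 ± 0.343 CPM). The median was -0.64 (camera adjusted p = 2.70e-11, adjusted p = 0.0762 with an estimated correlation). Nefl had 1709 ± 85.1 CPM in hearing and 1126 ± 184 CPM in deafened rats, and Tubb3 274 ± 13.4 and 179 ± 38.2 CPM. Scn4b, a sodium channel subunit, had 662 ± 45.2 and 404 ± 41.3 CPM, and Rbfox3 5.95 ± 0.467 and 3.15 ± 1.53 CPM. These 4 did not pass (edgeR adjusted p from 0.0854 to 0.256), and all 4 did without P32 hearing replicate 3, which enters this comparison through the shared estimate of the spread (9.68e-05 to 0.0356). Of 24 genes of type I and II spiral ganglion neurons 5 fell over all genes, and 9 fell and 3 rose adjusted over the list alone. The 5 were Calb2, Th, Ntng1, an axon guidance protein chosen after its values were seen, Lypd1, a modulator of nicotinic receptors (111 ± 8.26 to 53.1 ± 5.19 CPM), and the ephrin receptor Epha4 (223 ± 9.09 to 142 ± 6.27 CPM). That list had a median of -0.49 (camera adjusted p = 4.26e-04, adjusted p = 0.138 with an estimated correlation). The fall was deepest in P60 deaf replicate 3, which stood apart. The mean log2 CPM of the general list, less its mean over the 12 libraries, was -0.049, -0.346 and -0.555 in P60 deaf replicates 1, 2 and 3, and 0.212 to 0.303 in P60 hearing rats. With that library left out the general median was -0.55 (camera adjusted p = 1.61e-10, adjusted p = 0.115 with an estimated correlation). Elavl4 then no longer passed, and the general list still had 3 members lower and 1 higher over all genes. The list of spiral ganglion neurons then had a median of -0.26 and 3 falls (camera adjusted p = 0.00228, adjusted p = 0.262 with an estimated correlation).

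Of 40 neuronal ion channels, 4 fell (12 fell and 1 rose adjusted over the list alone; median -0.49, camera adjusted p = 9.95e-09, adjusted p = 0.171 with an estimated correlation). With P60 deaf replicate 3 left out the median was -0.41 (adjusted p = 0.25 with an estimated correlation). Among the 4 were the potassium channel subunit Kcnab2 (165 ± 9.01 to 82.8 ± 11.1 CPM) and the calcium-activated potassium channel Kcnma1 (1.42-fold). Of 39 synaptic genes 4 fell and 2 rose over all genes, and 11 fell and 2 rose adjusted over the list alone (median -0.36, camera adjusted p = 1.42e-06, adjusted p = 0.0797 with an estimated correlation). Syp, the vesicle protein synaptophysin (209 ± 7.94 to 116 ± 26.2 CPM), the glutamate receptor Grm7 (60.1 ± 7.85 to 36.1 ± 1.43 CPM) and the scaffold Dlg2 (1.54-fold) were lower. The NMDA receptor subunit Grin2b was higher (3.51 ± 0.0253 to 9.88 ± 1.62 CPM).

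Genes of axon injury were the third list that held with an estimated correlation (median 0.44, camera adjusted p = 6.27e-05, adjusted p = 0.0416 with an estimated correlation, and 0.0971 with P32 hearing replicate 3 left out). Of 23 members 5 rose and none fell over all genes, and 5 rose and 1 fell adjusted over the list alone. They were Atf3, the tubulin Tubb2b, chosen after its values were seen, Gadd45a, a DNA damage response gene (15.9 ± 1.03 to 42.5 ± 9.07 CPM), Gap43 and Jun (48.2 ± 2.79 to 86.3 ± 22.0 CPM). Of 24 activity-regulated early genes 4 rose (6 adjusted over the list alone): Atf3, Fos (8.90 ± 0.534 to 22.0 ± 3.97 CPM), the phosphatase Dusp6 (1.58-fold) and Bdnf, brain-derived neurotrophic factor (1.12 ± 0.519 to 3.56 ± 0.491 CPM). That list had a camera adjusted p of 0.00283 and an adjusted p = 0.235 with an estimated correlation. Bdnf, Lif (2.92-fold) and Fgf2 (2.21-fold) were the 3 of 26 neurotrophic factors and receptors to rise over all genes (6 rose and 2 fell adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0505).

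Glial genes moved in different ways. Of 26 genes of nonmyelinating and repair glia, 6 rose (9 adjusted over the list alone; median 0.24, camera adjusted p = 1.12e-05, adjusted p = 0.0708 with an estimated correlation), among them Btc (1.99 ± 0.330 to 13.7 ± 0.555 CPM), Gfap, Runx2 (27.0 ± 1.01 to 55.2 ± 6.15 CPM) and the progenitor factor Sox2 (19.6 ± 0.618 to 34.2 ± 2.13 CPM). Of 28 myelinating Schwann cell genes Pmp2, a fatty acid-binding protein of peripheral myelin, rose (15.8 ± 0.928 to 56.9 ± 20.8 CPM; 2 adjusted over the list alone). The list did not differ (median -0.10, camera adjusted p = 0.168). Mbp had 5399 ± 614 CPM in hearing and 4893 ± 218 CPM in deafened rats (edgeR adjusted p = 0.741). Cholesterol synthesis genes fell as a group (median -0.34, camera adjusted p = 9.77e-09, adjusted p = 0.0708 with an estimated correlation). Of its 25 genes 1 fell over all genes, and 7 did adjusted over the list alone.

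Cell cycle genes were higher (2 of 34, the replication factor Mcm3 and the spindle protein Prc1, over all genes and 9 adjusted over the list alone; median 0.46, camera adjusted p = 5.99e-09, adjusted p = 0.0762 with an estimated correlation). Of 23 fibroblast and matrix genes Thbs2, Timp1 and Lox rose, by 2.40-fold, 2.65-fold and 1.57-fold (camera adjusted p = 0.0113, adjusted p = 0.383 with an estimated correlation). Of 14 skeletal muscle genes Myl1 and the giant filament protein Neb (281 ± 22.1 to 149 ± 18.8 CPM) fell. The list did not differ (camera adjusted p = 0.186). Among 27 hair cell genes Ush1c, a scaffold of hair bundles, was lower (196 ± 13.5 to 120 ± 1.64 CPM) and Cabp2, a calcium sensor, was higher (0.570 ± 0.0615 to 1.71 ± 0.147 CPM; camera adjusted p = 0.0654). Otof had 3.18 ± 0.788 and 1.97 ± 0.334 CPM, and it, Myo7a, Slc26a5 and Pou4f3 did not pass (edgeR adjusted p from 0.426 to 0.948). Of 14 genes of nonsensory cells of the organ of Corti, Prox1, a homeobox factor also active in spiral ganglion neurons (130 ± 15.4 to 56.1 ± 6.91 CPM), and the Wnt pathway receptor Lgr5 (1.73-fold) fell. The list did not differ (camera adjusted p = 0.919). None of 24 endothelial and mural genes passed (camera adjusted p = 0.763).

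Stress genes moved singly at P60. The chaperone Hspb1 rose 2.84-fold, the metallothionein Mt2A from 13.0 ± 1.10 to 52.5 ± 9.02 CPM, the redox regulator Txnip 1.75-fold and the haem oxygenase Hmox1 1.51-fold, and the list of 23 did not pass (median -0.03, mean 0.19, camera adjusted p = 0.324). Met, the receptor for hepatocyte growth factor, was the 1 of 15 genes of the stria and ligament to rise (2.67-fold; list median 0.28, camera adjusted p = 0.0161, adjusted p = 0.149 with an estimated correlation). Of 55 oxidative phosphorylation genes Cox5a, a subunit of complex IV, was lower (1.39-fold; none adjusted over the list alone; median -0.24, camera adjusted p = 3.39e-07, adjusted p = 0.413 with an estimated correlation), and 29 were lower without P32 hearing replicate 3. The ribosomal list was higher (0 of 44, median 0.27, camera adjusted p = 0.00291, adjusted p = 0.671 with an estimated correlation), with 29 of the 44 past over all genes without that library. Of 17 cartilage genes Acan fell (1.62-fold, camera adjusted p = 0.0599), and Gfap and Runx2 were the 1 rise of 18 each among central glia (camera adjusted p = 0.0599) and osteoblasts (median below 0, mean 0.04, camera adjusted p = 0.910). Osteoclast, erythroid and mitochondrial genome genes gave none (camera adjusted p from 0.263 to 0.277), nor did sex-linked genes (median 0.03, mean -0.07, camera adjusted p = 0.919).

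Of the 38 lists 22 were past a camera adjusted p of 0.05 at P60, 16 higher and 6 lower, with 3 of them past it with an estimated correlation. By fry 19 of the 22 passed, 14 higher and 5 lower. Without P32 hearing replicate 3 the count of genes was 3321 (1596 higher, 1725 lower), all 578 were among them, and no list passed with an estimated correlation. The macrophage list then had 34 of 38 higher, toll-like receptors 22 of 29, complement 20 of 35, phagocyte lysosomes 17 of 25 (1 lower), interferon response 14 of 40, chemokines 14 of 33 (1 lower), class I 11 of 22, cell cycle 11 of 34, class II 7 of 10 and T and NK cells 6 of 22. Axon injury had 9 of 23 higher and 4 lower, repair glia 10 of 26 and 2, and early genes 8 of 24 higher. Lower were 21 of 26 general neuronal genes, 22 of 40 ion channels, 17 of 39 synaptic genes (3 higher), 11 of 24 genes of spiral ganglion neurons (3 higher) and 17 of 25 of cholesterol synthesis. With P60 deaf replicate 3 left out toll-like receptors had 2 of 29 higher, neurotrophic factors 1 of 26, interferon response 1 of 40, class II 1 of 10, T and NK cells 1 of 20, B cells 1 of 20 and repair glia 4 of 26. Class I, cell cycle, cholesterol synthesis, oxidative phosphorylation, cartilage and organ of Corti nonsensory lists then had no gene past the threshold. The lists of neurotrophic factors, central glia, granulocytes and osteoclasts then passed (camera adjusted p from 0.0301 to 0.0381). The count was 1264 by DESeq2, and 1940 when only the 6 libraries of that age were fitted. It was 375, 367 and 359 without P32 deaf replicate 1, 2 or 3, 158 and 317 without P60 deaf replicate 2 or 3, and 111, 334 and 146 without P60 hearing replicate 1, 2 or 3.

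**Figure D2:**
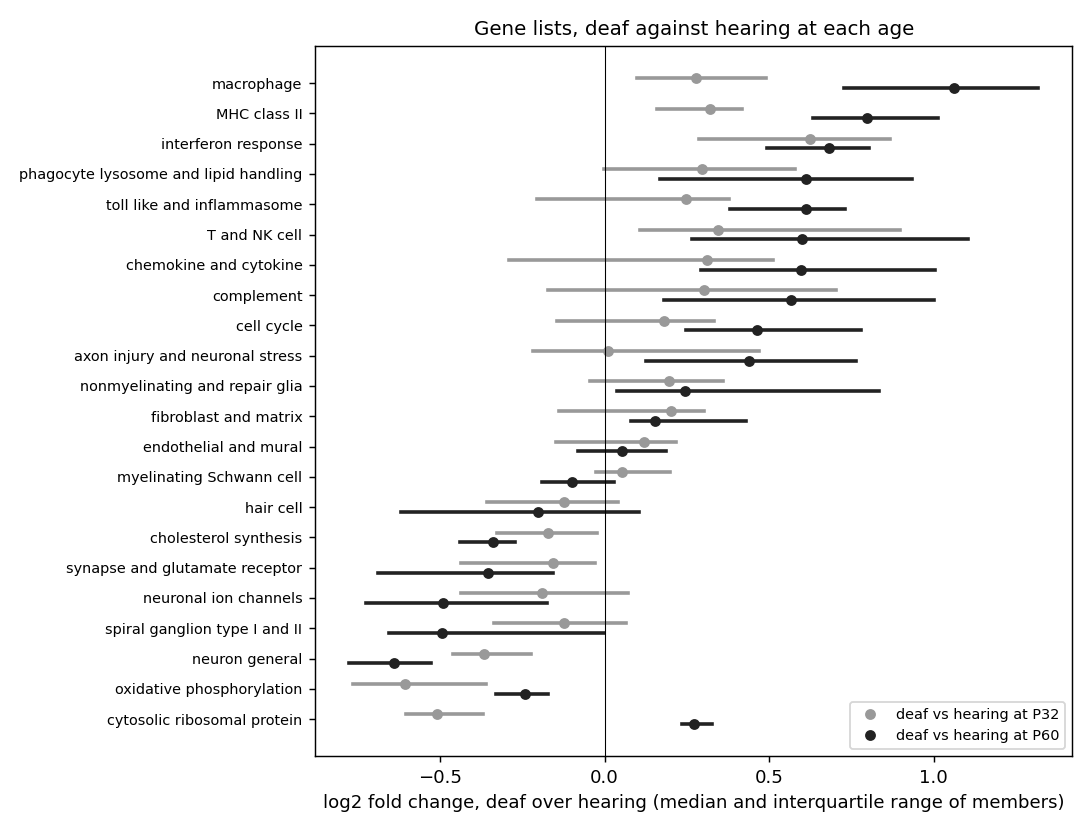
Log2 fold change of deafened over hearing rats for 22 of the gene lists, as the median (point) and interquartile range (bar) of the tested members, at P32 in grey and at P60 in black. At P60 the macrophage list lies highest, at 1.06, and the general neuronal list lowest, at -0.64, with the endothelial list at 0.05; the grey points of the ribosomal, mitochondrial energy and immune lists shift without P32 hearing replicate 3.

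The effect of deafening was compared between the ages. Of the 40 genes higher at P32, 35 were also higher at P60, against 0.897 for independent lists (Fisher's exact test p = 2.52e-53), and of the 16 lower at P32, 12 were also lower at P60, against 0.161 (Fisher's exact test p = 1.30e-21). The 47 shared genes included Gpnmb, Lgals3, Atf3, Gpr83, C3 and Cd68 among the higher and Calb2, Myl1, Ckmt2 and Hsd17b2 among the lower. None was past the threshold in opposite directions, and all 56 had the same sign at P60. With P32 hearing replicate 3 left out 1 gene passed in opposite directions. The 2 comparisons share no library, but they share 1 estimate of the spread for each gene. Genes of low spread are thus easier to call at both ages, and the expected numbers and Fisher p assume independent calls, which does not hold here. Across all 17789 genes, which are not independent replicates, the log2 fold changes at P32 and P60 had a Pearson correlation of 0.346 and a Spearman correlation of 0.248, and 0.55 and 0.546 without P32 hearing replicate 3.

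By a direct test of the difference between the effects, 0 genes were past an edgeR adjusted p of 0.05, with 805 at an unadjusted p under 0.05, 25 by DESeq2 and 0 by limma voom. Without P32 hearing replicate 3, 14 genes were past it, 13 of them with a larger log2 fold change at P60. Of the lists 21 differed by camera with the preset correlation and 0 with an estimated correlation (adjusted p from 0.490 to 0.693 with an estimated correlation). For the macrophage list the median difference, P60 minus P32, was 0.62 with all libraries and 0.33 without P32 hearing replicate 3.

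**Figure D3:**
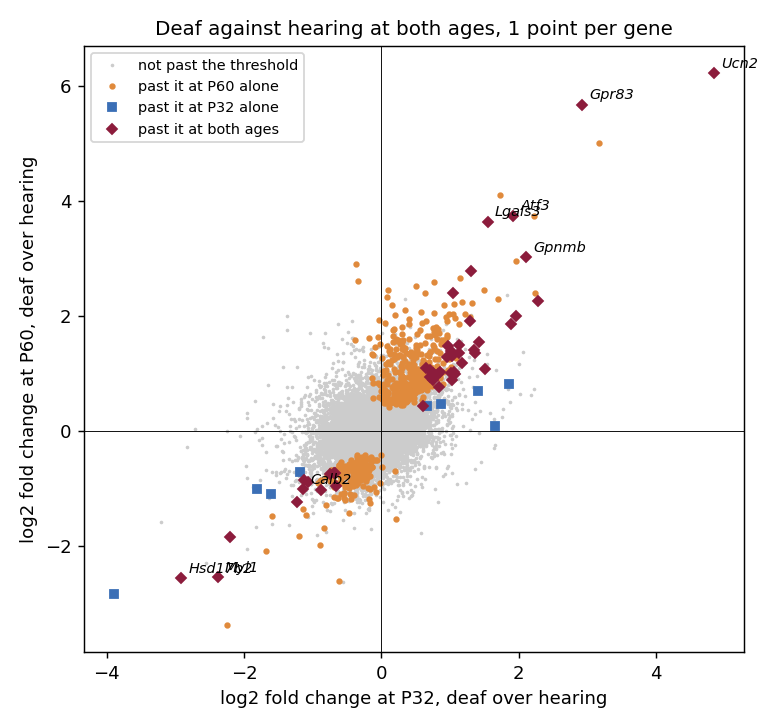
Log2 fold change of deafened over hearing rats at P32 (horizontal) and P60 (vertical), 1 point per tested gene, with genes past the edgeR threshold at both ages as dark red diamonds (47), at P32 alone as blue squares (9) and at P60 alone as orange points (531). The 47 shared genes lie at the lower left and upper right, with Ucn2, Gpr83, Atf3, Lgals3 and Gpnmb at the upper end and Hsd17b2 and Myl1 at the lower.

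From P32 to P60 a few genes of blood cells and cartilage were lower in the ganglion of hearing rats. As lists they did not pass with an estimated correlation (adjusted p = 0.0762 for erythroid, 0.202 for granulocyte and 0.105 for cartilage genes). Alox15 (ENSRNOG00000019183), a lipoxygenase of eosinophils and macrophages, went from 39.0 ± 5.03 to 3.05 ± 0.478 CPM (SD, n = 3 each), and the eosinophil granule genes Prg2 and Prg3 were 7.60-fold and 7.66-fold lower. Slc4a1, the anion exchanger of red blood cells, went from 14.7 ± 3.60 to 3.00 ± 0.455 CPM, and Kel, a red cell antigen, was 5.86-fold lower. Col11a1, a fibrillar collagen of cartilage, went from 423 ± 53.5 to 167 ± 22.1 CPM. Th rose 5.64-fold, from 2.50 ± 0.947 to 14.5 ± 1.09 CPM, and Ptgdrl, a prostaglandin D2 receptor-like gene, 1.99-fold from 4.03 ± 0.107 CPM. By edgeR 13 genes were past the threshold, those 2 higher and 11 lower.

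Of 17 erythroid genes Slc4a1 and Alas2, the first enzyme of haem synthesis in red cells, were lower in hearing rats at P60 over all genes and 13 adjusted over the list alone (median -1.37, camera adjusted p = 1.87e-10, adjusted p = 0.0762 with an estimated correlation). Granulocyte genes had a median of -1.29, with 0 of 13 past over all genes and 9 lower and 1 higher adjusted over the list alone (camera adjusted p = 8.40e-07, adjusted p = 0.202 with an estimated correlation). Osteoblast genes had a median of -0.67 (11 of 18 lower adjusted over the list alone; adjusted p = 0.201 with an estimated correlation) and cartilage genes of -0.42 (10 of 17; adjusted p = 0.105 with an estimated correlation). Cell cycle genes had a median of -0.76 (17 of 34 lower and 1 higher; adjusted p = 0.119 with an estimated correlation), cholesterol synthesis of -0.33 (12 of 25) and myelinating Schwann cells of -0.28 (6 of 28; adjusted p = 0.105 with an estimated correlation for both). Class II genes were higher (median 0.21, 4 of 10 adjusted over the list alone, camera adjusted p = 0.0192, adjusted p = 0.707 with an estimated correlation). The ribosomal list (-0.57) and oxidative phosphorylation (-0.38) were lower with all libraries (adjusted p = 0.807 with an estimated correlation for both) and at 0.10 and 0.02 without P32 hearing replicate 3. The cell cycle median was -0.34 and that of class II 0.62 without that library. Fibroblast genes were lower (median -0.14, camera adjusted p = 0.00736, adjusted p = 0.707 with an estimated correlation). In all 11 lists passed, 1 higher and 10 lower. With P32 hearing replicate 3 left out 18 did, 8 higher and 10 lower, among them macrophage genes, with a median of 0.07 against -0.29 (camera adjusted p = 7.14e-04), and interferon response, with 0.44 against 0.06. Without P32 hearing replicate 3 the count of genes was 41, and the erythroid list held with an estimated correlation (adjusted p = 0.0091 with an estimated correlation). The count of genes was 148 by DESeq2 and 1 when the 6 hearing libraries alone were fitted. It was 27 and 28 without P32 hearing replicate 1 or 2, and 1, 3 and 1 without P60 hearing replicate 1, 2 or 3.

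In deafened rats genes of red blood cells and cartilage were lower at P60 than at P32, and genes of phagocyte lysosomes and lipid handling were higher. That rise held with an estimated correlation with all libraries, but not with P32 hearing replicate 3 or P60 deaf replicate 3 left out (adjusted p = 0.0631 and 0.0668 with an estimated correlation). Alox15 went from 30.9 ± 4.75 to 3.30 ± 0.740 CPM, Slc4a1 from 11.9 ± 1.47 to 2.71 ± 1.30 CPM, and Col2a1, the main collagen of cartilage, from 270 ± 20.4 to 102 ± 35.9 CPM. Panx3, a channel of bone and cartilage cells, and Upk1b were 3.12-fold and 2.94-fold lower. Lgals3 rose 3.34-fold between the ages (30.3 ± 1.34 to 101 ± 25.8 CPM), Atf3 3.99-fold and Gpnmb 2.05-fold (45.1 ± 0.256 to 92.4 ± 19.2 CPM). The largest rises were in the inhibitory receptor Lilrb2 (9.15-fold), Gpr83 (5.98-fold), the glutamate receptor Grm5 (1.04 ± 0.288 to 6.36 ± 1.81 CPM), Tbx4 (5.22-fold) and Ucn2 (4.79-fold). By edgeR 49 genes were past the threshold, 31 higher and 18 lower. With the hearing rats they shared 1 of the 2 and 31 higher genes and 5 of the 11 and 18 lower genes, against 0.00349 and 0.0111 for independent lists, again with a shared spread.

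Of the 38 lists 26 passed in deafened rats, 14 higher and 12 lower, and 7 held with an estimated correlation. Myelinating Schwann cell genes were lower (2 of 28, Ncmap and Gjc3, over all genes and 11 adjusted over the list alone; adjusted p = 0.00228 with an estimated correlation). Cartilage genes were lower (5 of 17; 11 lower and 1 higher adjusted over the list alone; adjusted p = 0.00228 with an estimated correlation), among them Col11a1 (456 ± 4.88 to 174 ± 23.0 CPM), Acan, the aggregating proteoglycan of cartilage and of perineuronal nets (170 ± 14.4 to 89.8 ± 8.59 CPM), and Col9a1 (1.78-fold). Cholesterol synthesis was lower (20 of 25 adjusted over the list alone; adjusted p = 0.00518 with an estimated correlation), with Hmgcs1 (629 ± 29.7 to 308 ± 40.2 CPM) and Cyp51 (1.80-fold) past over all genes. Erythroid genes (8 of 17 adjusted over the list alone; adjusted p = 0.0188 with an estimated correlation) and osteoblast genes (11 lower and 1 higher of 18; adjusted p = 0.0485 with an estimated correlation) were lower as well. Higher were the genes of phagocyte lysosomes and lipid handling (8 of 25 adjusted over the list alone; adjusted p = 0.0437 with an estimated correlation) and of class II presentation (6 of 10; adjusted p = 0.0485 with an estimated correlation), the latter with Cd74 past over all genes (2.12-fold). The integrin Itgam of macrophages rose 1.87-fold, the chaperone Hspb1 2.24-fold and Gfap 1.90-fold. The count of genes was 557 without P32 hearing replicate 3, which enters through the shared spread, 223 by DESeq2, and 208 when the 6 deafened libraries alone were fitted. It was 8, 6 and 10 without P32 deaf replicate 1, 2 or 3, 31, 12 and 9 without P60 deaf replicate 1, 2 or 3, and 21 without P60 hearing replicate 1. Without P32 hearing replicate 3, the Schwann cell, cartilage and erythroid lists held with an estimated correlation, each with an adjusted p = 0.0146 with an estimated correlation. With P60 deaf replicate 3 left out, the Schwann cell, cartilage, cholesterol and erythroid lists held. The phagocyte, class II and osteoblast lists did not (adjusted p = 0.0668 with an estimated correlation for each of the 3). Over all genes 2 of 17 cartilage genes were then lower, and 0 of 28 Schwann cell, 0 of 25 cholesterol and 0 of 17 erythroid genes.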

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

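The test for a deafened sample under a hearing label was chosen only after the position of P32 hearing replicate 3 was seen, and the 14 genes below came from leaving that library out.

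For 21 lists the effect of deafening differed between the ages by camera's test of the difference, with the preset correlation. The median difference in log2 fold change, P60 minus P32, was 0.62 for macrophage genes, 0.32 for phagocyte lysosomes and lipid handling, 0.25 for complement, 0.36 for chemokines and cytokines, 0.28 for toll-like receptors, 0.42 for class II presentation and 0.55 for granulocytes. It was 0.28 for axon injury, 0.29 for nonmyelinating and repair glia, 0.54 for cell cycle, 0.27 for heat shock, 0.76 for ribosomal proteins, 0.41 for oxidative phosphorylation and 0.52 for the mitochondrial genome. Lists with a lower value at P60 were neuronal ion channels (-0.31), spiral ganglion neurons (-0.25), general neuronal genes (-0.21), synaptic genes (-0.20), cholesterol synthesis (-0.17), myelinating Schwann cells (-0.17) and cartilage (-0.14). None passed with an estimated correlation (camera adjusted p from 0.490 to 0.693). Of 50 drawn splits 12 gave as many lists, the real one included, with 23 as the highest other against the real 21. The draws shuffled all 12 libraries over the 4 groups, which mixes the effects of age and deafening into the spread. They thus cannot decide on chance, which is not excluded. With that hearing library (P32 replicate 3) left out the medians were 0.33 for macrophages, 0.16 for complement, 0.17 for cell cycle and axon injury, 0.14 for repair glia, chemokines and ribosomal proteins, 0.03 for heat shock, and -0.03 for both oxidative phosphorylation and the mitochondrial genome. They were -0.18 for ion channels, -0.13 for spiral ganglion neurons, -0.12 for synaptic genes and -0.27 for cartilage. The lists of chemokines (camera adjusted p = 0.0511), axon injury (0.0511), heat shock (0.0556), synapse (0.0561), oxidative phosphorylation (0.118), spiral ganglion neurons (0.131), granulocytes (0.280) and the mitochondrial genome (0.289) then no longer passed.

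For single genes the difference passed for 0 with 12 libraries by edgeR (805 at an unadjusted p under 0.05, 25 by DESeq2, 0 by voom). All 50 drawn splits gave 0 as well, which decides nothing, since any split reaches a real count of 0. Leaving out P32 hearing replicate 3, it passed for 14, with an edgeR adjusted p from 0.0169 to 0.0475 and from 0.0756 to 0.692 with all 12 libraries. The log2 differences were 3.06 for the glutamate receptor Grm5, 3.05 for Gpr83, 1.96 for Atf3, 1.95 for Lgals3, 1.37 for the phosphatase Dusp10, 1.35 for the adhesion molecule Chl1, 1.27 for S100a4, 1.23 for the metallothionein Mt2A and 1.5 for Glipr2. They were 1.12 for Fabp7, a fatty acid-binding protein of immature glia, 1.10 for the neuronal kinase Dclk1, 0.91 for Gfap and 0.86 for the kinase Plk2, and -1.04 for the proteoglycan Acan. Groups of 3 were not tested for outlying samples.

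P32 hearing replicate 3 drives part of these differences, and 3 technical explanations of its position were tested. Its 10 most abundant genes took 13.0% of its reads, against 6.47% to 7.98% in the others, so a few genes did not take most of the counts. Without those 10 genes its median correlation with the others stayed at 0.948, against at least 0.977. A correlation across this many genes can hardly move when 10 are removed, so it cannot decide on their part. Its score over the genes called at P60 was -1.93, near the other P32 hearing libraries (-2.14 and -2.26). It was below the P32 deafened ones (-1.12 to -1.04) by more than the range of the 3 hearing libraries (0.326). Those genes were called with this library in the shared spread, which can drop genes on which it departs from its group. The score thus cannot decide whether it is a deafened sample under its label. An earlier bound, from the other 2 hearing libraries alone, gave no decision and was replaced after the score was seen. Some lists went the other way. Its mean log2 CPM of macrophage genes, less the mean over libraries, was 0.263, against 0.115 to 0.211 in P32 deafened and -0.512 and -0.620 in the other P32 hearing libraries. That of general neuronal genes was -0.135, against -0.217 to -0.027 and 0.252 and 0.424. The score does not explain these. Against its group, 17 short mRNAs stood 1.55 log2 units above 17 giant mRNAs in it. The highest other library was P60 deaf replicate 3, at 0.404, which held the deepest neuronal fall at P60. Whether such a bias adds to that fall was not tested. For P32 hearing replicate 3, a bias toward short transcripts may explain part of its position. Differences in the animal or the dissection stay open and were not tested.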

How the results depend on the processing

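Alternatives with P32 hearing replicate 3 left out together with another change, with P60 deaf replicate 3 left out and an estimated correlation, with quality weights, with a robust fit and with recovered reads were chosen after seeing the data.

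Counts below are given for P32, P60, age in hearing rats, age in deafened rats and the interaction, in this order, against 56, 578, 13, 49 and 0 genes. DESeq2 gave 425, 1264, 148, 223 and 25. Fits of the compared groups alone gave 0, 1940, 1 and 208. The authors' normalized values of 11 libraries in limma trend gave 499, 3354, 30, 535 and 12 with a pseudocount of 1, and 497, 3376, 31, 552 and 12 with 5. A fold minimum of 2 left 236 at P60, as it removes genes by construction. No filter gave 21 for age in hearing rats and 2 for the interaction, and a replicate block 1 for the interaction. Other counts from these settings, from RLE, upper quartile, a stricter filter and voom stayed within 1.5 times. Leaving out 1 library gave 5 to 641, 111 to 3321, 1 to 41, 6 to 557, and 0 to 14. The highest of each came without P32 hearing replicate 3, where the biological coefficient of variation fell from 0.193 to 0.102.

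Among the added settings, DESeq2 on 11 libraries gave 1050, 3538, 163, 826 and 68, and a replicate block on them 653, 3737, 29, 652 and 14. Recovered whole reads gave 641, 3313, 41, 556 and 14. Without both P32 hearing replicate 3 and P60 deaf replicate 3 the counts were 2050, 3966, 240, 859 and 47, and voom with quality weights (0.0379 for P32 hearing replicate 3 and 0.254 for P60 deaf replicate 3) gave 2144, 3460, 356, 842 and 38. A robust fit stayed within 1.5 times. Beyond the spread that P32 hearing replicate 3 adds, the cause was not tested.

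For gene lists the counts were 23, 22, 11, 26 and 21. With an estimated correlation they were 0, 3, 0, 7 and 0, on 11 libraries 0, 0, 1, 3 and 0, and with P60 deaf replicate 3 left out 0, 4, 0, 4 and 0. Fry gave 0 at P32, 19 at P60, 7 and 9 for age in hearing and deafened rats, and 0 for the interaction. Without both libraries age in hearing rats gave 19. Leaving out 1 library gave 13 to 24 at P32 and 10 to 18 for age in hearing rats, and other counts stayed within 1.5 times. The Pearson correlation of the effects at the 2 ages, 0.346, was 0.838 over called genes alone and 0.209 to 0.55 with 1 library left out.

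Of the genes named, those with a reversed sign under some left-out library were not past the threshold with 12 libraries. Their ranges of log2 fold change were, at P32, Aif1 -0.148 to 0.75, Mbp -0.041 to 0.153, Pou4f3 -0.892 to 0.279, Ptprc -0.097 to 0.863 and Scn4b -0.552 to 0.085. At P60 they were Pou4f3 -0.564 to 0.702 and Slc26a5 -1.033 to 0.015. Of 157 calls of named genes 156 held with RLE, 147 with a replicate block and 154 of 154 with DESeq2, and of 1884 made with 1 library left out 1265 held and 619 kept their direction only.

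The 6 libraries of each comparison make 10 splits, too few for a share under 0.05. The real and the highest other counts of genes were 56 and 0 at P32, 578 and 0 at P60, 13 and 0 and 49 and 0 for age, and 3321 and 0 at P60 with 11 libraries, each reached by 1 split. For lists they were 23 and 19 at P32 (1 split), 22 and 22 at P60 (2 splits), 11 and 16 for age in hearing rats (5 splits) and 26 and 24 in deafened rats (1 split).

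The values do not settle whether replicate numbers pair the samples. Of 18 pairs of libraries with the same number, 6 had a residual correlation over 0.1 (-0.035 to 0.338). The median was 0.0745, against -0.031 for pairs with other numbers, and 8 of 12 libraries had their best match within their number. Without P32 hearing replicate 3 the medians were 0.016 and -0.012, and 6 of 11 libraries had such a match. The first lane alone was not run, since the columns hold 1 library each. Genes near the floor, such as Pou4f3, rest on few reads per library.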

Other observations

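The tests below, and the genes named in this paragraph, were chosen only after their values were seen. Hormone transcripts of the pituitary varied widely between libraries. Prl, prolactin, ranged from 0.646 CPM in P32 deaf replicate 3 to 65.9 CPM in P60 hearing replicate 1, and Gh1, growth hormone, from 1.64 to 29.4 CPM. Pomc, the precursor of corticotropin, had 15.8 CPM in P32 hearing replicate 3 and 1.11 to 3.59 CPM in the other libraries. Ptgds, a prostaglandin D2 synthase of fibrocytes and meninges, was abundant, at 8239 to 12190 CPM in 11 libraries and 17850 CPM in P32 hearing replicate 3. The Y-linked genes Kdm5d (32.5 to 128 CPM) and Eif2s3y (40.3 to 134 CPM) were present in all 12 libraries, so each held RNA from at least 1 male.

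The general neuronal list was lower in deafened rats at P60 with the preset correlation and by fry (fry adjusted p = 0.00867). It was not with an estimated correlation (camera adjusted p = 0.0762), and 3 of its 26 members fell over all genes. A loss of neurons alone, with every other cell type kept, was set against these data. With a uniformly lower share of neurons all neuronal genes would fall alike. The 26 members ran from -1.19 to 1.37 on the log2 scale (Cochran Q = 183), with Gap43 as the member at 1.37. This Q was past the 0.05 level, but Gap43 had been seen to rise before the test was chosen, so the list with it could not fall alike. Whole tissue does not show in which cell type Gap43 rose. This Q thus cannot decide on a lower share of neurons and does not bear on the other members. The quartiles were -0.77 and -0.53, and 23 of the 26 lay below 0. For the 25 other members, tested after Gap43 had been seen to stand apart, Q was 48.4, past the 0.05 level. It was 98.1, also past it, with P32 hearing replicate 3 left out, and 36.2, short of it, with P60 deaf replicate 3 left out. For these 25 a uniformly lower share cannot be told apart from changes that differ between genes, as the verdict turns on 1 library. Dilution would raise every other cell type alike. The lower quartile of the macrophage list lay 0.543 above the higher of the upper quartiles of the endothelial and Schwann cell lists. That argues against dilution as the whole source of the macrophage rise, and does not bear on whether neurons were lost. A loss of some neurons, with or without changed transcription in those left, together with a rise in macrophages, stays open.

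Myl1, Neb, Srl and Ckmt2, known from striated muscle, were lower in deafened rats at P60. Less skeletal muscle in the dissected tissue would need its abundant transcripts at a level to match. In hearing libraries Mylpf reached at most 1.37% of Neb, Tnnt3 0.695% and Acta1 0.658%, which argues against it for Neb. The ratios were taken to Neb alone, which had 281 CPM in P60 hearing rats, against 5.81 CPM for Ckmt2. Less muscle was thus not tested for Myl1, Srl and Ckmt2. A uniformly lower share of neurons would bring them to the median of the general neuronal list. Since the 4 were picked at P60, they were set against that median in the P32 libraries, in place of an earlier test at P60, with a bound of 2.5 SE for 4 genes. The smaller of the distances with 12 and with 11 libraries was 5.82 SE below it for Myl1 and 6.09 SE for Ckmt2, which argues against a lower share as the whole cause for both, though they were among the largest falls at P32 too. It was 2 SE for Srl, with 12 libraries, against 4.73 SE with 11. For Neb it was 1.62 SE, with 11 libraries, against 3.04 SE with 12. At P60, where the 4 were picked, the distances with 12 and 11 libraries were 4.94 and 9.48 SE for Srl. They were 1.5 and 2.88 SE for Neb. For Srl and Neb a uniformly lower share of neurons cannot be told apart from a fall of their own, as the smaller distance at P32 stays within the bound. A cell type of the ganglion that makes these transcripts may be reduced, which was not tested.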
